A study of Mus musculus with 21 samples.

How the data were processed

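Lung epithelial cells and lung fibroblasts were profiled with 3'SAGE-seq, a method that sequences 1 short tag near the 3' end of each polyadenylated transcript, on an Ion Proton instrument. Per the labels' protocols, lungs of C57BL/6 mice carrying a Col1a2-GFP transgene, which marks collagen-producing fibroblasts with a green fluorescent protein, were digested enzymatically. The suspension was stained for CD31 (encoded by Pecam1), CD45 (Ptprc), Ter119, CD146 (Mcam) and Epcam and depleted on magnetic beads. Live epithelial cells were then sorted as negative for those 4 lineage markers and for GFP and positive for Epcam, and live fibroblasts as negative for the lineage markers and Epcam and positive for GFP. The epithelial label at E18.5 names the lineage and Epcam gates but not the GFP gate that the protocol gives for the sort in general. Poly(A) RNA was amplified before library construction.

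There were 21 libraries, 2 at each of E18.5, P0.5, P2, P7 and P28 in both cell types and 1 fibroblast library at P56. The labels number the replicates but name no separate animals, so the p-values measure only the spread between these samples, which may be technical (but see Xist at P28 below). Libraries of the same group differed by more than sampling noise: the chi-square statistic of their reads divided by its degrees of freedom was 4.64 to 10.6, over genes with at least 10 reads in the pair.

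The deposited values are a signal per gene, tag counts divided by a factor for the library as a whole, listed in 1 table per library. Bowtie2 2.2.5, R 3.4.0 and the mouse genome build mm10 are named by the submitters' processing notes, and the normalisation itself is not given in the sources used here. Within each library every value was a whole multiple of 1 constant. Dividing by it gave whole reads for 100% of values above 0, within a tolerance of 0.01 of a read, with a largest deviation of 4.93e-05. The recovered depth was 2146071 to 5729829 reads per library. A count of 0 allows up to 3 reads, which is 0.403 to 1.37 value units for 1 library, and the bounds for a group of libraries take 3 reads over the whole group. Amplified reads carry no molecular identifiers and are not independent molecules, so these floors cover counting error only.

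The epithelial tables list 23869 genes, of which 993 are at 0 in every epithelial library, and the fibroblast tables list 21170, with 20004 genes in both. The sums of the deposited values differ from library to library (769260 in fibroblasts at P56 to 1155140 in epithelial E18.5 replicate 2), and the tables of the 2 cell types were normalised separately. Stage comparisons within a cell type therefore used the deposited values, and comparisons between cell types used recovered reads over the 20004 shared genes, scaled together with TMM (trimmed mean of M-values) factors to a common library size of 1e6 reads in the 20 libraries of the 5 shared stages, called joint CPM.

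The tests had been planned for raw counts, with the quasi-likelihood test of edgeR. Because the unit is normalised, the test used was limma (3.58.1, R 4.3.3) with a mean-variance trend on log2(value + 1), as foreseen for that case, with genes at a value of 3 or more in at least 2 libraries. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Each cell type was fitted with 1 mean per stage (10 epithelial or 11 fibroblast libraries, 5 residual degrees of freedom in each fit), and the cell types were compared in a joint fit of 20 libraries (10 residual degrees of freedom). Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05, and all tests of genes were two-sided. The P56 group has 1 library, which is assumed to vary like the other fibroblast groups. Differences between cell types in a change over time were tested as interaction terms. In data simulated from real means and depths, the test recovered 100 of 100 genes changed 4-fold for epithelium E18.5 to P28 (11575 genes). It recovered 98 in fibroblasts (11641 genes) and 92 for the interaction (12596 genes). At 2-fold these were 59, 61 and 16, not split by expression level.

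The 36 gene lists of lung cell types, cell types that the gates should remove, and pathways were fixed before the data were examined, as were the groups, the tests, the alternatives and the rule for named genes, except where stated. Lists with at least 4 tested members were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. Camera with an estimated correlation is given beside each list called, because it ends most of the calls: 36 of 164 list calls hold with it. The named genes were the sort genes (Epcam, Col1a2, Pecam1, Ptprc, Mcam), the genes past the threshold with the largest fold changes among those with a mean of at least 50 in the higher group, leaving out predicted genes, and up to 4 members of each described list with the smallest p past the threshold, or 2 where none passed. The second part of the rule took 10 genes in each direction for the cell types and for E18.5 to P28, 5 for E18.5 to P0.5, and 3 otherwise. Where a gene was at 0 in every library of a group, a fold is given as a bound against the floor, and a list's median is also given with such members at their bound where that changes it.

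Alternatives were median-of-ratios scaling of recovered reads, pseudocounts of 0.5 and 5, no filter on low values, reads thinned to the smallest library, the edgeR 4.0.16 quasi-likelihood test and DESeq2 1.42.0 on recovered reads, all 21 libraries in 1 fit, the replicate number as a block, and each library left out in turn. Fits without E18.5, without P28 and without the P56 library and a replicate block within stages were added after seeing the data. Leaving out 1 of 2 libraries leaves a group with a single library, assumed to vary like the others. Of 23869 epithelial and 21170 fibroblast gene names, 18125 and 16615 were found in GENCODE vM21 (GRCm38, the assembly also called mm10), which gave coordinates and transcript lengths. Genes with near-identical copies, such as the haemoglobin genes, the histone gene Hist1h2ao, and Rplp2 with its pseudogene Rplp2-ps1, can share tags and are uncertain one by one.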

Results

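The 21 libraries measured gene expression in sorted mouse lung epithelial cells and Col1a2-GFP fibroblasts around birth (E18.5, P0.5 and P2), during postnatal growth (P7), at P28 and, for fibroblasts, at P56. Each group held 2 libraries except fibroblasts at P56, which had 1. The recovered depth was 2282124 to 5602529 reads per library in the epithelium and 2146071 to 5729829 in fibroblasts, with 14980 to 17580 genes above 0 per library. The 10 most abundant genes took 11.5% to 20.8% of the reads of a library. Values are mean ± SD of the deposited, normalised values of the 2 libraries of a group (n = 2), or of joint CPM where the cell types are compared. Changes are log2 fold changes on the log2(value + 1) scale. Largest changes are ranked among called genes with a mean of at least 50 in the higher group, without predicted genes. Adjusted p-values are from limma for genes and from camera for gene lists. With an estimated correlation 128 of 164 list calls were lost, so most list changes hold only at the preset correlation. The number of list members called when adjusted over the list alone is given where it differs from the number over all genes.

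The first comparison asked which genes separate the epithelium from fibroblasts over the 5 stages that both share. Genes of surfactant and of alveolar type 2 cells, which make and secrete surfactant, headed the genes higher in the epithelium. The surfactant protein gene Sftpc (GRCm38, chromosome 14, 70520949 to 70524081, minus strand) was at 9267 ± 3657 joint CPM in the epithelium and 8.10 ± 6.72 in fibroblasts (n = 10 libraries each), a log2 difference of 10.16 (SE 0.19) (adjusted p = 6.31e-21). Sftpb (9.92), the complement C5 gene Hc (9.85), lysozyme 1 (Lyz1, 9.31), the proton pump subunit gene Atp6v1c2 (8.98) and Pla2g1b (8.95) followed. Next were Sfta2 (8.93), Sftpa1 (8.87), the chemokine gene Cxcl15 (8.85) and the transporter gene Slco4c1 (8.73). Fibroblasts were higher in genes of the extracellular matrix. Type I collagen chain Col1a1 (chromosome 11, 94936224 to 94953042, plus strand) was at 1553 ± 600.4 joint CPM in fibroblasts and 9.36 ± 6.15 in the epithelium, a difference of -7.48 (SE 0.13). Elastin (Eln) was at 1895 ± 1483 and 18.5 ± 17.6 (-7.02 (SE 0.19)). Spondin 1 (Spon1, -7.80) led, with Col3a1 (-7.42), integrin alpha 8 (Itga8, -7.34) and Col1a2 (-7.29). The C1 inhibitor gene Serping1 (-7.28), matrix Gla protein (Mgp, -7.10), the glutamate receptor gene Gria3 (-7.09) and biglycan (Bgn, -7.06) completed the 10 largest differences in that direction. Of the genes used for the sort, Epcam was at 131 ± 96.7 in the epithelium against 2 reads in all fibroblast libraries together, and Col1a2 was at 17.7 ± 16.3 against 2334 ± 774. Ptprc was higher in the epithelium by 0.82 (SE 0.25), and Mcam did not pass (-0.29 (SE 0.24), adjusted p = 0.297). Epcam, and Col1a2 through its reporter, were used to select the cells, so their differences check the sort and are no finding. In all, 8349 of 13386 genes differed, 4344 higher in the epithelium and 4005 higher in fibroblasts (4195 and 3738 with edgeR on recovered reads).

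**Figure D1:**
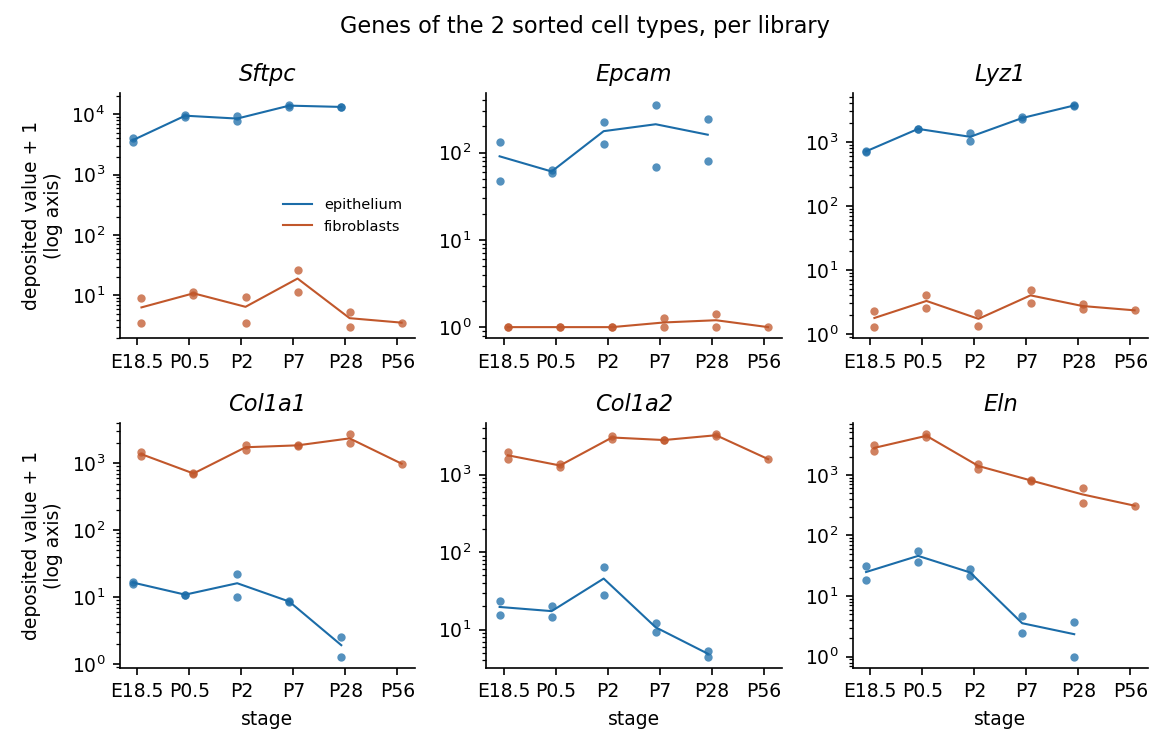
Deposited values of 3 epithelial genes (Sftpc, Epcam, Lyz1) and 3 matrix genes (Col1a1, Col1a2, Eln) by stage, on a log axis of value + 1. Points are libraries and lines join the stage means. The tables of the 2 cell types were normalised separately, so levels are to be compared within a cell type, and the difference between cell types on joint CPM is 10.16 for Sftpc and -7.48 for Col1a1 (log2).

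The fixed gene lists divided along the same line. All 19 tested alveolar type 2 genes were higher in the epithelium (median log2 difference 8.33, adjusted p = 3.22e-18, adjusted p = 0.00208 with an estimated correlation). So were all 18 genes of alveolar type 1 cells, the flat cells of gas exchange (5.24, adjusted p = 4.94e-13, adjusted p = 0.00374 with an estimated correlation). All 7 club cell genes (3.71, adjusted p = 4.73e-05, adjusted p = 0.0179 with an estimated correlation) and all 6 ciliated cell genes (2.42, adjusted p = 1.67e-04, adjusted p = 0.0277 with an estimated correlation) were on the same side. General epithelial genes were higher in 13 of 13 (adjusted p = 1.18e-11, adjusted p = 0.0025 with an estimated correlation). Cdh1 was at 179.9 ± 26.8 joint CPM against 1 read in all fibroblast libraries together. Ion and water transport genes had 10 of 11 higher and 1 lower (adjusted p = 8.55e-08, adjusted p = 0.00208 with an estimated correlation), and the sodium channel subunit Scnn1a differed by 6.96. Cholesterol synthesis genes had 17 of 19 higher and 0 lower (adjusted p = 9.59e-06, adjusted p = 0.00787 with an estimated correlation). Fatty acid synthesis genes had 10 of 13 higher and 1 lower (adjusted p = 1.81e-04, adjusted p = 0.00902 with an estimated correlation), the desaturase Scd1 at 7.43. MHC class II genes of antigen presentation had 7 of 7 higher and 0 lower (adjusted p = 2.35e-05, adjusted p = 0.0417 with an estimated correlation), Cd74 at 5.75. Leukocyte genes, which the CD45 gate should have removed, were higher in the epithelium in 6 of 7 (median 0.98, adjusted p = 0.0344, adjusted p = 0.354 with an estimated correlation). Tyrobp was at 185 ± 243 joint CPM against 8.99 ± 7.61.

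Fibroblasts were higher in all 13 mesenchymal genes (adjusted p = 1.18e-11, adjusted p = 0.00161 with an estimated correlation), Vim by -4.79 as epithelium minus fibroblasts. All 15 collagen and matrix genes were on that side (median -6.40, adjusted p = 2.65e-13, adjusted p = 0.00849 with an estimated correlation). Elastic fibre genes were lower in the epithelium in 15 of 16 (adjusted p = 3.63e-10, adjusted p = 0.00902 with an estimated correlation). Of myofibroblast genes the same held for 14 of 15 (adjusted p = 5.55e-07, adjusted p = 0.0147 with an estimated correlation). Complement and chemokine genes leaned to fibroblasts in 11 of 13 (adjusted p = 5.50e-05, adjusted p = 0.00849 with an estimated correlation), pericyte genes in 6 of 7 (adjusted p = 0.00524, adjusted p = 0.0267 with an estimated correlation). Lipofibroblast genes did so in 8 of 10 (adjusted p = 0.00102, adjusted p = 0.0262 with an estimated correlation). That list held the fatty acid transporter Cd36 as an exception, higher in the epithelium by 6.29 (SE 0.15). Wnt signalling genes were lower in the epithelium in 7 of 10 (adjusted p = 0.00168, adjusted p = 0.0166 with an estimated correlation). The hedgehog ligand gene Shh was higher in the epithelium (7.58 (SE 0.21)). In fibroblasts 8 of 10 hedgehog genes were higher, the ligand-binding antagonist Hhip among them (-6.60 (SE 0.21), list adjusted p = 0.00168, adjusted p = 0.0267 with an estimated correlation). Adventitial fibroblast genes were lower in the epithelium in 8 of 13 (adjusted p = 0.0265, adjusted p = 0.0508 with an estimated correlation). Imprinted and fetal growth genes were lower in 8 of 14 with 5 higher (adjusted p = 0.0345, adjusted p = 0.0604 with an estimated correlation), with Mest higher in fibroblasts (-4.79) and Meg3 in the epithelium (1.60). Immediate early genes were lower in the epithelium in 12 of 17 (2 higher and 13 lower adjusted over the list alone, adjusted p = 0.0118, adjusted p = 0.371 with an estimated correlation). Lists of cell cycle, glycolysis, antioxidant, interferon, MHC class I, glucocorticoid response and retinoic acid genes did not pass. Nor did endothelial, mesothelial, erythroid, neutrophil and lymphocyte, and sort genes. Cardiomyocyte genes and basal and neuroendocrine genes had under 4 tested members and no list test.

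From E18.5 to P0.5 some surfactant genes rose in the epithelium and some genes of fetal growth and lipid synthesis fell, list calls that were lost with an estimated correlation. The 5 largest rises were of ribosomal protein genes and a pseudogene of one, which no fixed list covers. Rps28 (chromosome 17, 33819027 to 33824562, minus strand) went from 23.8 ± 6.55 to 558 ± 71.5, a change of 4.52 (SE 0.33) (adjusted p = 1.02e-05). Rplp2 (4.35), Rplp2-ps1 (4.15), Rps29 (3.87) and Rpl38 (3.87) followed. Fstl1, a secreted follistatin-like glycoprotein (chromosome 16, 37776873 to 37836514, plus strand), fell from 8241 ± 389 to 1356 ± 45.8 (-2.60 (SE 0.18)). The imprinted RNA H19 fell from 194 ± 13.9 to 9.0 ± 2.33 (-4.30 (SE 0.54)). The macrophage gene C1qa (-3.18), Gipr (-3.07) and Sdf2l1 (-2.79) were the other genes with the largest falls. Alveolar type 2 genes rose in 7 of 19 (11 adjusted over the list alone, adjusted p = 5.36e-06, adjusted p = 0.165 with an estimated correlation). Sftpc was at 3754 ± 432 and 9495 ± 617 (1.34 (SE 0.20)).

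Glucocorticoid-responsive genes rose in the same step in 6 of 11 (adjusted p = 3.86e-04, adjusted p = 0.165 with an estimated correlation). Among them were Mt2 (2.96), Errfi1 (1.64), Cebpd (1.51) and Klf9 (1.27). Fatty acid synthesis genes fell in 5 of 12 (1 higher and 7 lower adjusted over the list alone, adjusted p = 9.55e-04, adjusted p = 0.165 with an estimated correlation). Glycolysis and hypoxia genes fell in 8 of 16 (1 higher and 10 lower adjusted over the list alone, adjusted p = 3.86e-04, adjusted p = 0.165 with an estimated correlation). Imprinted and fetal growth genes fell in 3 of 13 (1 higher and 6 lower adjusted over the list alone, adjusted p = 0.013, adjusted p = 0.165 with an estimated correlation). Cell cycle genes were lower in 4 of 19 (5 adjusted over the list alone, adjusted p = 0.0148, adjusted p = 0.203 with an estimated correlation). Ciliated cell genes fell in 5 of 10 with 1 higher (1 higher and 6 lower adjusted over the list alone, adjusted p = 0.0311, adjusted p = 0.627 with an estimated correlation), endothelial genes in 2 of 4 (3 adjusted over the list alone, adjusted p = 0.0297, adjusted p = 0.201 with an estimated correlation). Lipofibroblast genes rose in 3 of 8 (adjusted p = 0.0148, adjusted p = 0.165 with an estimated correlation). The erythroid list rose in 1 of 7 (7 adjusted over the list alone, adjusted p = 0.0033, adjusted p = 0.627 with an estimated correlation), and its haemoglobin genes are uncertain one by one. The test called 1740 of 12143 genes, 879 higher and 861 lower (915 and 872 with edgeR). Leaving out E18.5 replicate 1 or 2, or P0.5 replicate 1 or 2, left 925, 1118, 660 and 616 genes.

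Between P0.5 and P2 the epithelium rose in MHC class II genes and fell in some glucocorticoid-responsive genes. H2-Eb1, an MHC class II chain (chromosome 17, 34305867 to 34316674, plus strand), rose from 152 ± 10.9 to 1239.8 ± 244 (3.0 (SE 0.23), adjusted p = 1.10e-05). The class II list was higher in 5 of 7 (6 adjusted over the list alone, adjusted p = 6.52e-09, adjusted p = 0.0397 with an estimated correlation). Cd74, the chaperone of class II molecules, went from 19.7 ± 5.42 to 115 ± 12.7, and H2-Aa and H2-Ab1 rose by 2.80 and 2.71. Of leukocyte genes, 0 of 9 (median 0.53, adjusted p = 0.414) passed. Of neutrophil and lymphocyte genes it was 1 of 4 (2 adjusted over the list alone, median 1.76 (2.36 with members at 0 set to their bound), adjusted p = 0.0826), and of the sort genes 0 of 4 (2 adjusted over the list alone, median 1.38, adjusted p = 0.12). Glucocorticoid-responsive genes fell in 6 of 11 (1 higher and 7 lower adjusted over the list alone, adjusted p = 1.78e-05, adjusted p = 0.18 with an estimated correlation). The transcription factor gene Zbtb16 went from 145 ± 18.3 to 25.7 ± 1.47 (-2.45 (SE 0.21)), with Fkbp5 at -3.32, Klf9 at -1.71 and Per1 at -1.16. Fatty acid synthesis genes rose in 5 of 12 (adjusted p = 0.00249, adjusted p = 0.18 with an estimated correlation). Ciliated cell genes fell in 3 of 10 (4 adjusted over the list alone, adjusted p = 0.0152, adjusted p = 0.484 with an estimated correlation). The lipofibroblast list fell in 2 of 8 (1 higher and 6 lower adjusted over the list alone, adjusted p = 0.0131, adjusted p = 0.18 with an estimated correlation). Among genes with a mean of at least 50, the largest rises besides H2-Eb1 were in Fam84a (2.79) and Snhg11 (2.66). The largest falls among such genes were in Tecrl (-3.41), the urea cycle enzyme gene Ass1 (874 ± 1.88 to 90.7 ± 11, -3.26 (SE 0.17)) and Rps28 (-2.68). The test called 1071 genes, 623 higher and 448 lower (524 and 496 with edgeR). Without P0.5 replicate 1, P0.5 replicate 2 or P2 replicate 1 it called 199, 109 and 366.

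From P2 to P7 cell cycle and MHC class II genes rose in the epithelium while some blood and leukocyte genes fell. Cell cycle genes were higher in 5 of 19 (14 adjusted over the list alone, adjusted p = 3.34e-12, adjusted p = 0.0197 with an estimated correlation). The topoisomerase gene Top2a went from 7.78 ± 3.91 to 64.9 ± 1.98 (2.98 (SE 0.35)). Class II genes rose in 5 of 7 (7 adjusted over the list alone, adjusted p = 7.99e-10, adjusted p = 0.0197 with an estimated correlation), Cd74 reaching 431 ± 33.6 (1.90 (SE 0.21)). Over the same step leukocyte genes fell in 2 of 9 (3 adjusted over the list alone, median -1.24 (-2.59 with members at 0 set to their bound), adjusted p = 5.38e-04, adjusted p = 0.345 with an estimated correlation). Tyrobp, an adaptor of myeloid and natural killer cells, was at 157 ± 133 at P2, with its libraries far apart, and at 1 read over both P7 libraries. Il1b also had 1 read at P7, and Slfn2 went from 70.7 ± 71.6 to 0, its P2 libraries also far apart. Neutrophil and lymphocyte genes fell in 1 of 4 (adjusted p = 0.00635, adjusted p = 0.263 with an estimated correlation). Erythroid genes fell in 5 of 7 (7 adjusted over the list alone, adjusted p = 1.06e-10, adjusted p = 0.147 with an estimated correlation). Of the sort genes, 1 of 4 (2 adjusted over the list alone, adjusted p = 0.0192, adjusted p = 0.186 with an estimated correlation) fell.

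Some mesenchymal and matrix genes fell in the epithelium at this step. The mesenchymal list was lower in 3 of 7 (4 adjusted over the list alone, adjusted p = 2.51e-05, adjusted p = 0.09 with an estimated correlation). Collagen and matrix genes were lower in 4 of 12 (8 adjusted over the list alone, adjusted p = 1.88e-06, adjusted p = 0.09 with an estimated correlation), with Col1a2 from 44.6 ± 25.3 to 9.70 ± 2.10. Elastic fibre genes were lower in 2 of 10 (4 adjusted over the list alone, adjusted p = 0.00262, adjusted p = 0.199 with an estimated correlation). Alveolar type 2 genes were higher in 2 of 19 with 1 lower (9 higher and 2 lower adjusted over the list alone, adjusted p = 0.00305, adjusted p = 0.223 with an estimated correlation). Fatty acid synthesis genes rose in 2 of 12 (6 adjusted over the list alone, adjusted p = 4.18e-04, adjusted p = 0.09 with an estimated correlation). Genes of fetal growth and imprinting fell in 3 of 13 (1 higher and 5 lower adjusted over the list alone, adjusted p = 0.00262, adjusted p = 0.117 with an estimated correlation). Club cell genes fell as a list (1 of 11, 5 adjusted over the list alone, adjusted p = 0.00218, adjusted p = 0.308 with an estimated correlation). Ciliated cell genes did too, with 0 of 10 (5 adjusted over the list alone, adjusted p = 0.00218, adjusted p = 0.306 with an estimated correlation) past the threshold. Immediate early genes rose in 2 of 17 (3 adjusted over the list alone, adjusted p = 0.0192, adjusted p = 0.442 with an estimated correlation). Glucocorticoid-responsive genes were higher in 1 of 11 (adjusted p = 0.00934, adjusted p = 0.263 with an estimated correlation). Slit3 (3.13) and Hist1h2ao (2.65) were, with Top2a, the largest rises. The step had 451 called genes, 188 higher and 263 lower (233 and 344 with edgeR). There were 221, 140 and 172 without P2 replicate 1, P7 replicate 1 and P7 replicate 2.

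**Figure D2:**
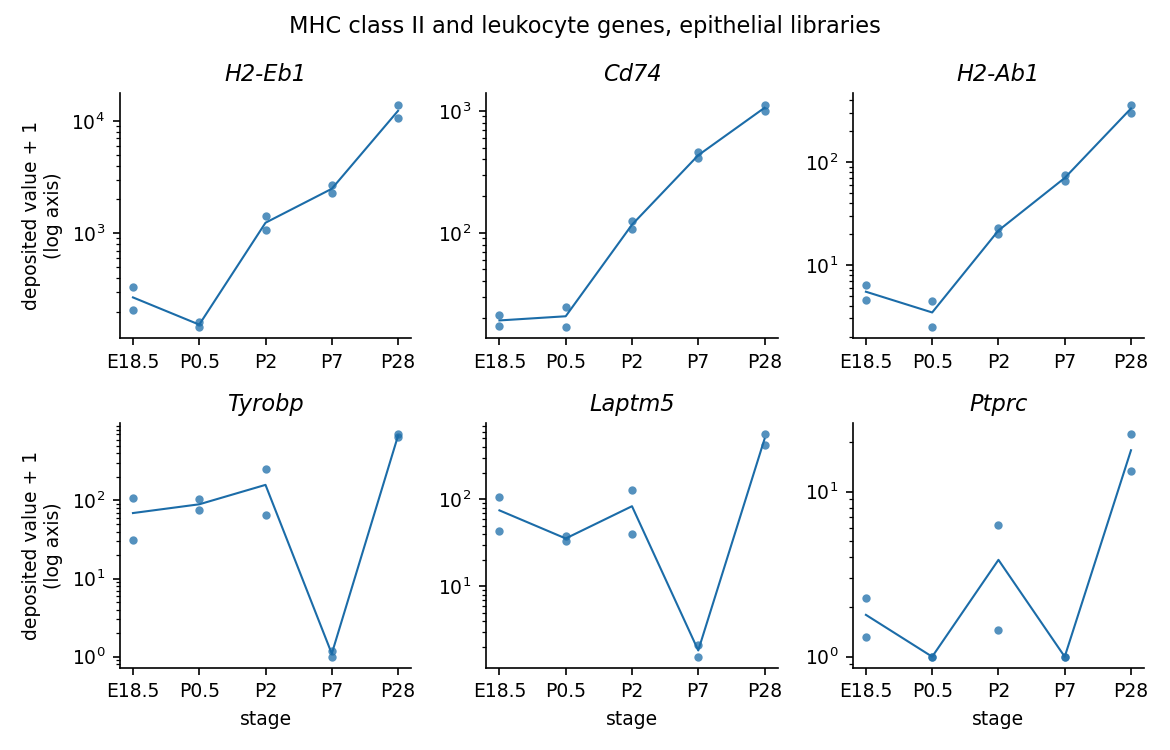
Deposited values in the epithelial libraries of 3 MHC class II genes (H2-Eb1, Cd74, H2-Ab1) and 3 leukocyte genes (Tyrobp, Laptm5, Ptprc) by stage, on a log axis of value + 1. Points are libraries and lines join the stage means. The class II genes rose from P0.5 on, while Tyrobp had 1 read and Ptprc 0 over both P7 libraries, and all 6 genes were higher at P28.

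From P7 to P28 the epithelial libraries rose in some airway, antigen presentation, interferon and leukocyte genes and fell in fetal growth genes. Club cell genes were higher in 8 of 11 (9 adjusted over the list alone, adjusted p = 4.64e-13, adjusted p = 0.0618 with an estimated correlation). Scgb1a1, the main secretory protein of club cells, went from 376 ± 50.2 to 2717 ± 69.6 (2.86 (SE 0.32)). Ciliated cell genes were higher in 6 of 10 (10 adjusted over the list alone, adjusted p = 1.75e-07, adjusted p = 0.105 with an estimated correlation). Imprinted and fetal growth genes fell in 7 of 13 (9 adjusted over the list alone, median -1.49 (-1.68 with members at 0 set to their bound), adjusted p = 8.74e-14, adjusted p = 0.0176 with an estimated correlation). Meg3 went from 861 ± 163 to 74.0 ± 1.24 and Igf2bp3 from 61.1 ± 4.23 to 1.44 ± 0.403. Fstl1 fell from 384 ± 3.64 to 17.0 ± 1.64 (-4.42 (SE 0.18), adjusted p = 3.96e-09), and the laminin chain Lamb1 changed by -4.55 (SE 0.25). Leukocyte genes rose in 6 of 9 (7 adjusted over the list alone, median 3.21 (4.40 with members at 0 set to their bound), adjusted p = 7.68e-10, adjusted p = 0.125 with an estimated correlation), with Tyrobp at 672 ± 43.4 and Laptm5 from 0.840 ± 0.397 to 491 ± 94.3. Ptprc, the CD45 gene of the depletion, went from 0 to 16.8 ± 6.33, at least 48.1-fold higher. The chemokine Ccl5 went from 0 to 787 ± 117, at least 2249.9-fold, and Il1b had 1 read at P7 and 480.4 ± 88.5 at P28. Neutrophil and lymphocyte genes rose in 2 of 4 (adjusted p = 3.45e-04, adjusted p = 0.131 with an estimated correlation), erythroid genes in 5 of 7 (adjusted p = 7.94e-05, adjusted p = 0.257 with an estimated correlation).

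The immune gene lists moved in the same direction as the leukocyte genes at P28. MHC class II genes rose in 4 of 7 (median 1.29, adjusted p = 5.36e-06, adjusted p = 0.0618 with an estimated correlation), beside the leukocyte median of 3.21. H2-Eb1 went from 2489.8 ± 287 to 12336 ± 2361. MHC class I genes rose in 2 of 8 (5 adjusted over the list alone, adjusted p = 7.59e-04, adjusted p = 0.0618 with an estimated correlation). Interferon-stimulated genes rose in 5 of 12 (6 adjusted over the list alone, adjusted p = 2.13e-06, adjusted p = 0.0618 with an estimated correlation). Immediate early genes rose in 3 of 17 (8 adjusted over the list alone, adjusted p = 1.72e-05, adjusted p = 0.174 with an estimated correlation). Antioxidant genes rose in 2 of 13 (adjusted p = 2.75e-04, adjusted p = 0.0618 with an estimated correlation). Glucocorticoid-responsive genes rose in 3 of 11 (5 adjusted over the list alone, adjusted p = 0.0012, adjusted p = 0.137 with an estimated correlation), with Zbtb16 from 26.1 ± 5.64 to 327 ± 12.2. Alveolar type 1 genes fell in 5 of 18 (6 adjusted over the list alone, adjusted p = 0.00231, adjusted p = 0.271 with an estimated correlation). General epithelial genes fell in 1 of 15 (adjusted p = 0.0274, adjusted p = 0.271 with an estimated correlation). Collagen and matrix genes were lower in 4 of 12 (1 higher and 7 lower adjusted over the list alone, adjusted p = 3.74e-04, adjusted p = 0.105 with an estimated correlation). Elastic fibre genes fell in 4 of 10 (adjusted p = 4.93e-07, adjusted p = 0.0618 with an estimated correlation), Lox at -2.89. Hedgehog genes fell in 2 of 7 (adjusted p = 0.00237, adjusted p = 0.0823 with an estimated correlation), Shh at -2.06. The mesenchymal list had a median of -1.12 but a positive mean, 0.51, and did not pass (adjusted p = 0.353). The step had 884 called genes, 591 higher and 293 lower (630 and 341 with edgeR). Without P7 replicate 1, P7 replicate 2, P28 replicate 1 and P28 replicate 2 there were 481, 566, 451 and 406.

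Across the whole course, from E18.5 to P28, the epithelium lost fetal growth genes and raised some secretory, type 2 and immune genes. Fstl1 fell from 8241 ± 389 to 17.0 ± 1.64, a change of -8.84 (SE 0.18) (adjusted p = 5.13e-13). The Notch-family ligand Dlk1 and H19 fell to 0, at least 395-fold and 383-fold lower. Mesothelin (Msln, 436 ± 11.2 to 2.31 ± 1.62), the imprinted RNA Rian (-6.21), Igf2bp3 (-5.66) and Gdpd2 (-5.42) came next. Mslnl (-4.74), Tecrl (-4.70) and podocalyxin (Podxl, -4.56) completed the largest falls. Imprinted and fetal growth genes fell in 12 of 13 (median -2.72 (-3.18 with members at 0 set to their bound), adjusted p = 2.04e-15, adjusted p = 0.0108 with an estimated correlation). The airway secretory gene Scgb3a1 (chromosome 11, 49663610 to 49665118, plus strand) rose from 6.17 ± 6.89 to 4214 ± 1411 (9.60 (SE 1.19)), Tff2 by 6.27 (SE 0.76) and Ramp3 by 6.38 (SE 0.45). Club cell genes were higher in 9 of 11 with 1 lower (adjusted p = 2.93e-05, adjusted p = 0.149 with an estimated correlation), Scgb1a1 by 5.53 (SE 0.32). Alveolar type 2 genes rose in 12 of 19 (adjusted p = 1.49e-07, adjusted p = 0.0563 with an estimated correlation), with Sftpa1 from 204 ± 3.27 to 2816 ± 361. Lyz1 rose by 2.38, Sftpd by 2.58 and Lyz2, which macrophages also express, by 4.29. Alveolar type 1 genes fell in 13 of 18 with 1 higher (adjusted p = 3.16e-07, adjusted p = 0.115 with an estimated correlation), Rtkn2 at -2.37 (SE 0.21) and Cav1 at -1.92 (SE 0.23). General epithelial genes fell in 9 of 15 (adjusted p = 0.00162, adjusted p = 0.149 with an estimated correlation), with Krt19 from 7116 ± 205 to 917 ± 97.2. Epcam was at 89.8 ± 61.4 and 159.6 ± 114 and did not pass (adjusted p = 0.414).

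Beside Scgb3a1, Ramp3 and Tff2, the 10 largest rises by P28 held 7 more genes. The chemokines Ccl5 (8.23) and Ccl22 (7.22), Timd4 (6.70) and Rgs1 (6.08) rose. Il12b, Klrd1 and Ms4a1, genes of dendritic, natural killer and B cells, went from 0 to at least 195-fold, 169-fold and 160.1-fold above the floor. Leukocyte genes were higher in 6 of 9 (median 2.09, adjusted p = 0.0115, adjusted p = 0.412 with an estimated correlation), and Ptprc went from 0.793 ± 0.663 to 16.8 ± 6.33. Neutrophil and lymphocyte genes rose in 2 of 4 (adjusted p = 0.0112, adjusted p = 0.209 with an estimated correlation). Beside these, MHC class II genes rose in 7 of 7 (median 5.55, adjusted p = 6.64e-12, adjusted p = 0.0108 with an estimated correlation). Cd74 went from 18.1 ± 2.84 to 1058 ± 92.5 and H2-Eb1 from 267 ± 87.4 to 12336 ± 2361. MHC class I genes rose in 6 of 8 (adjusted p = 1.21e-04, adjusted p = 0.0563 with an estimated correlation). Interferon-stimulated genes were higher in 6 of 12 (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.00162, adjusted p = 0.115 with an estimated correlation). Complement and chemokine genes rose in 4 of 6 (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.0154, adjusted p = 0.149 with an estimated correlation). Immediate early genes rose in 7 of 17 (adjusted p = 5.16e-04, adjusted p = 0.209 with an estimated correlation). Cell cycle genes were higher in 6 of 19 (7 adjusted over the list alone, adjusted p = 0.00243, adjusted p = 0.115 with an estimated correlation). Antioxidant genes rose in 7 of 13 (8 adjusted over the list alone, adjusted p = 5.49e-04, adjusted p = 0.0563 with an estimated correlation). The glucocorticoid-responsive list rose in 7 of 11 (adjusted p = 0.00189, adjusted p = 0.149 with an estimated correlation).

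Some matrix, hedgehog and transport genes fell in the epithelium between E18.5 and P28. Collagen and matrix genes were lower in 7 of 12 (adjusted p = 1.43e-05, adjusted p = 0.0635 with an estimated correlation). Elastic fibre genes were lower in 8 of 10 (median -2.77 (-2.90 with members at 0 set to their bound), adjusted p = 2.80e-07, adjusted p = 0.0563 with an estimated correlation). The fibroblast reporter gene Col1a2 went from 18.6 ± 5.79 to 3.90 ± 0.598 (-1.97 (SE 0.39)). The matrix members stood at a median of 2.17% of the fibroblast level at E18.5 and mesenchymal genes at 2.07% (2.18% and 1.92% at P2). Hedgehog genes fell in 3 of 7 (adjusted p = 0.00553, adjusted p = 0.107 with an estimated correlation), with Shh from 919 ± 31.6 to 154 ± 2.50. Ion and water transport genes fell in 4 of 12 with 1 higher (2 higher and 5 lower adjusted over the list alone, adjusted p = 0.0416, adjusted p = 0.209 with an estimated correlation), with the water channel Aqp1 from 102 ± 16.0 to 4.24 ± 0.528. Glycolysis and hypoxia genes fell in 5 of 16 (2 higher and 5 lower adjusted over the list alone, adjusted p = 0.0266, adjusted p = 0.149 with an estimated correlation). Ciliated cell genes fell in 3 of 10 (adjusted p = 0.0266, adjusted p = 0.369 with an estimated correlation). In all 3020 of 12143 genes were called, 1643 higher and 1377 lower (1548 and 1439 with edgeR), and 1838 without P28 replicate 2. A test of any difference over the 5 stages called 4286 epithelial genes. Of these, 1127 had their highest mean at E18.5, 771 at P0.5, 515 at P2, 657 at P7 and 1216 at P28.

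**Figure D3:**
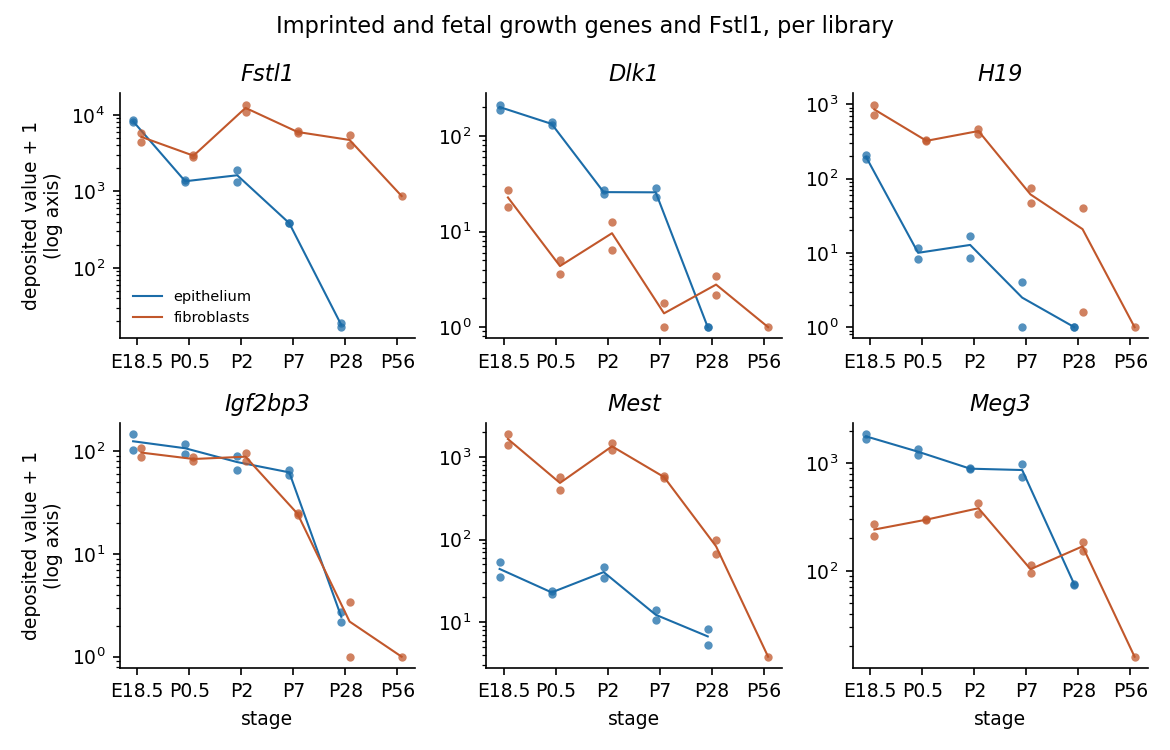
Deposited values of Fstl1 and of 5 imprinted or fetal growth genes (Dlk1, H19, Igf2bp3, Mest, Meg3) by stage in both cell types, on a log axis of value + 1. Points are libraries and lines join the stage means, and levels are to be compared within a cell type. Fstl1 fell by 8.84 on the log2 scale in the epithelium from E18.5 to P28, where Dlk1 and H19 reached 0.

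From E18.5 to P0.5 many immediate early and some chemokine and glucocorticoid-responsive genes rose in fibroblasts. Handling effects were not tested. Ybx3, a nucleic acid binding protein gene (chromosome 6, 131364855 to 131388476, minus strand), rose from 5.44 ± 0.147 to 313 ± 25.0 (5.60 (SE 0.42), adjusted p = 4.83e-08). S100a6 rose by 4.57 (SE 0.33), Galnt15 by 3.90 (SE 0.36) and the chemokine Cxcl2 by 4.20 (SE 0.20). Cxcl3 went from 4.17 ± 0.464 to 117 ± 7.94 (4.51 (SE 0.21)). Immediate early genes rose in 14 of 17 with 2 lower (median 1.49, adjusted p = 7.61e-12, adjusted p = 0.159 with an estimated correlation). Klf4 went from 232 ± 74.2 to 1569.8 ± 33.8. Complement and chemokine genes rose in 6 of 12 (adjusted p = 5.29e-04, adjusted p = 0.145 with an estimated correlation). Glucocorticoid-responsive genes rose in 5 of 11 (6 adjusted over the list alone, adjusted p = 5.29e-04, adjusted p = 0.145 with an estimated correlation). Adventitial genes rose in 2 of 12 (4 adjusted over the list alone, adjusted p = 0.00696, adjusted p = 0.154 with an estimated correlation). Lipofibroblast genes rose in 3 of 9 (4 adjusted over the list alone, adjusted p = 0.0106, adjusted p = 0.22 with an estimated correlation). Erythroid genes rose in 5 of 7 (adjusted p = 5.29e-04, adjusted p = 0.301 with an estimated correlation). Fatty acid synthesis genes fell in 5 of 13 (adjusted p = 0.00151, adjusted p = 0.145 with an estimated correlation), with the desaturase Scd2 from 1585 ± 99.3 to 268 ± 6.76 (-2.56 (SE 0.17)). Cell cycle genes were lower in 2 of 18 with 1 higher (median -0.98, adjusted p = 0.00148, adjusted p = 0.198 with an estimated correlation). Adam12 (-3.51), Hist1h2ao (-2.61), Ccdc8 (-2.57) and Hs6st3 (-2.47) were, with Scd2, the largest falls. The test called 1839 of 11954 genes, 962 higher and 877 lower (979 and 784 with edgeR). It called 935, 867 and 676 without E18.5 replicate 2, P0.5 replicate 1 and P0.5 replicate 2.

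**Figure D4:**
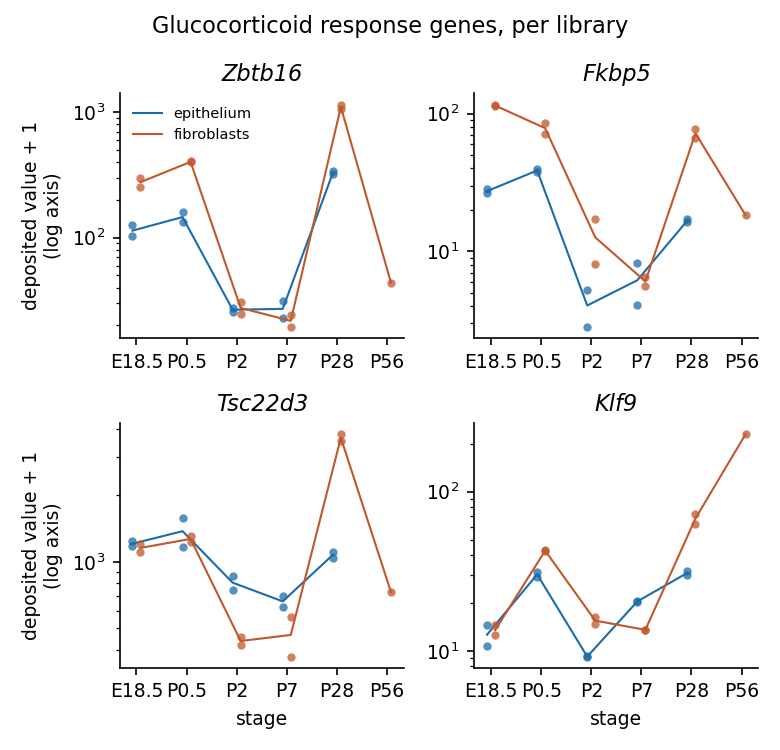
Deposited values of 4 glucocorticoid-responsive genes (Zbtb16, Fkbp5, Tsc22d3, Klf9) by stage in both cell types, on a log axis of value + 1. Points are libraries and lines join the stage means, and levels are to be compared within a cell type. Zbtb16 fell after P0.5 in both cell types and was higher again at P28.

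Between P0.5 and P2 fibroblasts raised many collagen genes and lowered some lipofibroblast and glucocorticoid-responsive genes. Collagen and matrix genes rose in 10 of 15 (12 higher and 2 lower adjusted over the list alone, adjusted p = 9.52e-07, adjusted p = 0.203 with an estimated correlation). Col1a1 went from 705 ± 29.3 to 1742 ± 191, Col1a2 from 1309.6 ± 96.5 to 3009 ± 199 and decorin (Dcn) from 279 ± 7.36 to 1108 ± 165. Elastic fibre genes went both ways, higher in 6 of 16 with 2 lower (adjusted p = 0.0212, adjusted p = 0.256 with an estimated correlation). Elastin (Eln) went from 4398 ± 385 to 1395 ± 182 (-1.66 (SE 0.22)). Myofibroblast genes were higher in 6 of 15 with 3 lower (adjusted p = 0.0394, adjusted p = 0.256 with an estimated correlation), smooth muscle actin Acta2 by 2.82 (SE 0.26). Lipofibroblast genes fell in 6 of 9 with 1 higher (1 higher and 7 lower adjusted over the list alone, adjusted p = 2.73e-05, adjusted p = 0.203 with an estimated correlation). Inmt went from 325 ± 32.3 to 12.2 ± 3.32 and Tcf21 from 541 ± 72.8 to 97.4 ± 19.7. Glucocorticoid-responsive genes fell in 5 of 11 with 1 higher (2 higher and 5 lower adjusted over the list alone, adjusted p = 0.0119, adjusted p = 0.203 with an estimated correlation), with Zbtb16 from 401 ± 5.81 to 26.5 ± 4.35 (-3.88 (SE 0.20)). Cell cycle genes rose in 7 of 18 (9 adjusted over the list alone, adjusted p = 0.00121, adjusted p = 0.203 with an estimated correlation). Complement and chemokine genes rose in 7 of 12 (adjusted p = 0.0394, adjusted p = 0.233 with an estimated correlation). Immediate early genes fell in 6 of 17 with 3 higher (3 higher and 9 lower adjusted over the list alone, adjusted p = 0.0212, adjusted p = 0.548 with an estimated correlation). The epithelial type 1 list fell in 5 of 14 with 1 higher (2 higher and 8 lower adjusted over the list alone, adjusted p = 0.0225, adjusted p = 0.256 with an estimated correlation). The club list fell in 2 of 4 (adjusted p = 0.0212, adjusted p = 0.203 with an estimated correlation).

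The largest single changes of that step in fibroblasts were rises of Fat3 (4.12), Hist1h2ao (3.73) and Csf3 (3.71). The largest falls were of Wipf3 (-5.41), Galnt15 (-5.08) and Ybx3, which returned to 9.20 ± 0.948 (-4.94). The test called 2025 genes, 1164 higher and 861 lower (1070 and 934 with edgeR). Without P0.5 replicate 1, P0.5 replicate 2, P2 replicate 1 and P2 replicate 2 it called 1024, 789, 1037 and 1129. From P2 to P7 imprinted and fetal growth genes fell in 8 of 14 (10 adjusted over the list alone, adjusted p = 3.40e-08, adjusted p = 0.049 with an estimated correlation), with Mest from 1343 ± 165 to 569.8 ± 25.7. Fxyd3 (4.50), Palmd (4.03) and Nnmt (2.61) rose most among genes with a mean of at least 50. The haemoglobin genes Hbb-bt, Hbb-b2 and Hbb-bs fell most (-4.58, -4.55 and -4.51). The erythroid list fell in 5 of 7 (7 adjusted over the list alone, adjusted p = 5.88e-13, adjusted p = 0.144 with an estimated correlation). Cell cycle genes rose in 4 of 18 (adjusted p = 0.00139, adjusted p = 0.195 with an estimated correlation). Lipofibroblast genes rose in 4 of 9 with 1 lower (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.0149, adjusted p = 0.264 with an estimated correlation). Mesothelial genes rose in 3 of 6 (6 adjusted over the list alone, adjusted p = 1.03e-06, adjusted p = 0.144 with an estimated correlation), Msln by 4.15. Glycolysis and hypoxia genes fell in 3 of 16 (adjusted p = 0.0149, adjusted p = 0.195 with an estimated correlation). Immediate early genes fell in 4 of 17 (1 higher and 4 lower adjusted over the list alone, adjusted p = 8.45e-04, adjusted p = 0.481 with an estimated correlation). Glucocorticoid-responsive genes fell in 3 of 11 with 1 higher (1 higher and 5 lower adjusted over the list alone, adjusted p = 0.0109, adjusted p = 0.195 with an estimated correlation). The step had 794 called genes, 282 higher and 512 lower (337 and 522 with edgeR). There were 262, 400, 503 and 514 without P2 replicate 1, P2 replicate 2, P7 replicate 1 and P7 replicate 2.

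From P7 to P28 glucocorticoid-responsive, adventitial, complement and interferon genes rose in fibroblasts and some cell cycle genes fell. Glucocorticoid-responsive genes were higher in 9 of 11 (10 adjusted over the list alone, median 2.32, adjusted p = 3.08e-11, adjusted p = 0.0152 with an estimated correlation). Zbtb16 (chromosome 9, 48654297 to 48836222, minus strand) went from 20.7 ± 3.35 to 1101 ± 66.3 (5.67 (SE 0.20), adjusted p = 7.39e-13). Adventitial genes were higher in 10 of 12 with 1 lower (adjusted p = 2.60e-08, adjusted p = 0.0152 with an estimated correlation), with gelsolin (Gsn) from 746 ± 83.8 to 8697 ± 1049. Complement and chemokine genes rose in 11 of 12 (12 adjusted over the list alone, adjusted p = 2.23e-12, adjusted p = 0.0152 with an estimated correlation), Cxcl14 by 5.16 (SE 0.47). Interferon-stimulated genes rose in 8 of 11 (9 adjusted over the list alone, median 2.35 (2.83 with members at 0 set to their bound), adjusted p = 4.61e-07, adjusted p = 0.0178 with an estimated correlation). Immediate early genes rose in 15 of 17 (adjusted p = 3.62e-09, adjusted p = 0.122 with an estimated correlation). MHC class I genes rose in 5 of 8 (adjusted p = 2.22e-04, adjusted p = 0.0775 with an estimated correlation). Antioxidant genes rose in 3 of 14 (5 adjusted over the list alone, adjusted p = 0.00161, adjusted p = 0.159 with an estimated correlation). Glycolysis and hypoxia genes rose in 8 of 16 (adjusted p = 0.00496, adjusted p = 0.0775 with an estimated correlation). Fatty acid synthesis genes rose in 3 of 13 (5 adjusted over the list alone, adjusted p = 0.0177, adjusted p = 0.117 with an estimated correlation).

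Leukocyte genes rose in the P28 fibroblasts in 2 of 4 (adjusted p = 0.0362, adjusted p = 0.183 with an estimated correlation), beside the interferon and MHC genes that rose in the same libraries. Laptm5 was at 53.9 ± 46.2 and Tyrobp at 16.9 ± 9.33. Erythroid genes rose in 5 of 7 (adjusted p = 6.88e-06, adjusted p = 0.151 with an estimated correlation). Club genes rose in 1 of 4 (2 adjusted over the list alone, adjusted p = 0.0204, adjusted p = 0.122 with an estimated correlation), the retinal dehydrogenase gene Aldh1a1. Cell cycle genes fell in 9 of 18 (14 adjusted over the list alone, adjusted p = 4.80e-07, adjusted p = 0.0505 with an estimated correlation), with Top2a from 114 ± 9.28 to 16.4 ± 6.86. Imprinted and fetal growth genes fell in 7 of 14 with 1 higher (1 higher and 9 lower adjusted over the list alone, median -1.10 (-1.17 with members at 0 set to their bound), adjusted p = 1.33e-05, adjusted p = 0.0298 with an estimated correlation). Inmt rose from 6.26 ± 1.17 to 812 ± 109 (6.81 (SE 0.24)), Crispld2 by 6.45 (SE 0.39) and Aldh1a1 by 5.80 (SE 0.48). Camk1g and Ddah1 changed by -5.21 and -5.14, and Col25a1, a transmembrane collagen, went from 81.4 ± 4.13 to 1 read. The step had 2491 called genes, 1356 higher and 1135 lower (1317 and 1166 with edgeR). It had 1548 and 1563 without P7 replicate 1 and P28 replicate 1.

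Over the whole course from E18.5 to P28 fibroblasts raised chemokine, complement and adventitial genes. Cxcl3 (chromosome 5, 90786103 to 90789600, plus strand) rose from 4.17 ± 0.464 to 842 ± 123, a change of 7.34 (SE 0.21) (adjusted p = 1.93e-14). Cxcl2 (6.89), Cxcl10 (6.53), the extracellular superoxide dismutase Sod3 (6.43) and Mamdc2 (6.14) followed. After them came the matrix protein gene Prelp (6.05), Aldh1a1 (6.02), Crispld2 (5.99) and Aldh1a7 (5.97). Metallothionein Mt2 had 3 reads over both E18.5 libraries and reached 217 ± 65.6. Adventitial genes rose in 11 of 12 (median 3.78, adjusted p = 4.79e-11, adjusted p = 0.00873 with an estimated correlation), with Cd34 from 37.4 ± 24.3 to 664 ± 1.16. Complement and chemokine genes rose in 11 of 12 (12 adjusted over the list alone, median 4.79, adjusted p = 2.79e-12, adjusted p = 0.00873 with an estimated correlation). Imprinted and fetal growth genes fell in 11 of 14 (12 adjusted over the list alone, median -2.44, adjusted p = 7.12e-11, adjusted p = 0.00873 with an estimated correlation). Mest went from 1645 ± 336 to 81.8 ± 22.5 and Igf2bp3 from 95.6 ± 13.2 to 1.20 ± 1.69. Immediate early genes were higher in 14 of 17 (adjusted p = 5.99e-09, adjusted p = 0.178 with an estimated correlation). Glucocorticoid-responsive genes rose in 8 of 11 with 1 lower (8 higher and 2 lower adjusted over the list alone, adjusted p = 4.77e-05, adjusted p = 0.0686 with an estimated correlation). Antioxidant genes rose in 8 of 14 (10 adjusted over the list alone, adjusted p = 2.36e-04, adjusted p = 0.178 with an estimated correlation). MHC class I genes were higher in 6 of 8 (7 adjusted over the list alone, adjusted p = 4.28e-04, adjusted p = 0.113 with an estimated correlation). Interferon-stimulated genes rose in 5 of 11 (adjusted p = 0.00519, adjusted p = 0.113 with an estimated correlation). Mesothelial genes rose in 5 of 6 (6 adjusted over the list alone, adjusted p = 0.00599, adjusted p = 0.279 with an estimated correlation).

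Among the genes that fell in fibroblasts from E18.5 to P28, Col25a1 (chromosome 3, 130131501 to 130599877, plus strand) went from 259 ± 17.8 to 1 read over both P28 libraries. Shisa6 fell to 0, at least 158-fold lower. H19 went from 848 ± 196 to 19.8 ± 27.2, with the P28 libraries far apart. Aspg (-5.97), Igf2bp3 (-5.71), Adamdec1 (-5.63) and Frrs1l (-5.53) followed. Camk1g (-5.36) and Cldn10 (-4.44) completed the largest falls, with the angiotensinogen gene Agt between them, and Col1a2 rose by 0.87 (SE 0.17). The collagen and matrix list (8 of 15 higher and 4 lower, adjusted p = 0.133) and the elastic fibre list (6 of 16 higher and 6 lower, adjusted p = 0.835) did not pass. Myofibroblast (5 of 15 higher and 4 lower, adjusted p = 0.835) and pericyte genes (1 of 7 higher and 0 lower, adjusted p = 0.901) did not either. In all 4020 of 11954 genes were called, 2237 higher and 1783 lower (2190 and 1774 with edgeR). The test of any difference over the 5 shared stages called 5845 fibroblast genes. Of these, 1265 had their highest mean at E18.5, 912 at P0.5, 1048 at P2, 783 at P7 and 1837 at P28.

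**Figure D5:**
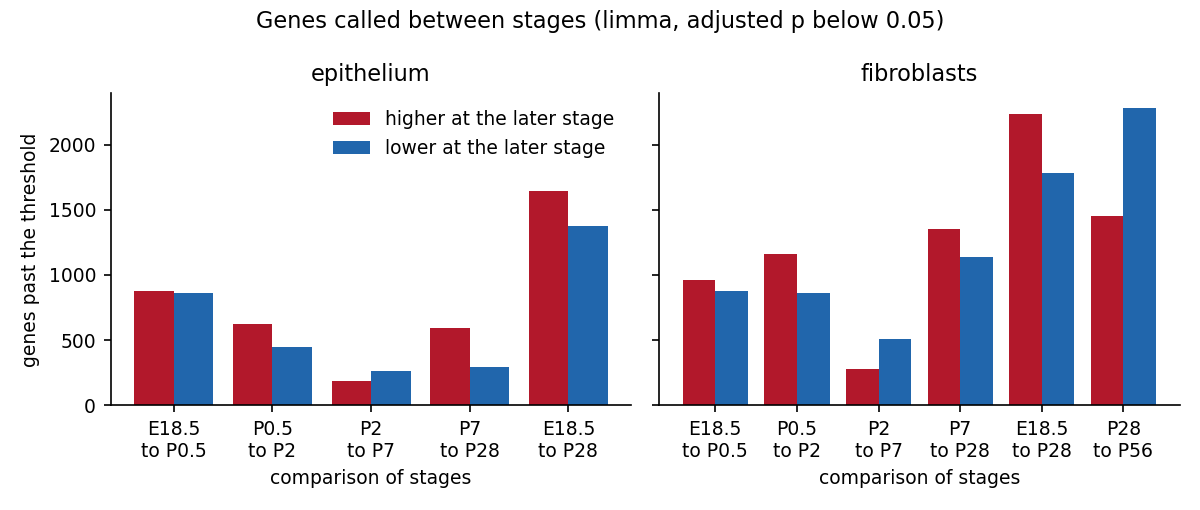
Number of genes past the adjusted p threshold for each step between stages, higher and lower, in the epithelium and in fibroblasts. The P2 to P7 step has the fewest in both cell types (451 and 794).

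The single P56 fibroblast library differed from the 2 P28 libraries in immediate early and matrix genes, a comparison with no replicate at P56. Jun was at 619.6 ± 35.2 at P28 and 7376 at P56 (3.57 (SE 0.21)). Immediate early genes were higher in 9 of 17 with 3 lower (adjusted p = 4.95e-04, adjusted p = 0.36 with an estimated correlation). The matrix glycoprotein gene Sparc, the most abundant gene at P28, was at 55522 ± 510.3 and 2661 (-4.38 (SE 0.26)). Collagen and matrix genes were lower in 10 of 15 (1 higher and 10 lower adjusted over the list alone, adjusted p = 2.23e-04, adjusted p = 0.228 with an estimated correlation), Col1a2 at -1.02 (SE 0.21). Igfbp3 (chromosome 11, 7206086 to 7213923, minus strand) went from 125 ± 3.92 to 3095 (4.62 (SE 0.25), adjusted p = 4.44e-10). Hoxb4 (5.01) and Chst7 (4.42) were the other largest rises. Glucocorticoid-responsive genes were lower in 5 of 11 with 1 higher (2 higher and 6 lower adjusted over the list alone, adjusted p = 0.025, adjusted p = 0.228 with an estimated correlation). Myofibroblast genes were lower in 7 of 15 (adjusted p = 0.0106, adjusted p = 0.228 with an estimated correlation). Glycolysis and hypoxia genes were lower in 7 of 16 (9 adjusted over the list alone, adjusted p = 0.00906, adjusted p = 0.228 with an estimated correlation). Imprinted genes were lower in 4 of 14 (5 adjusted over the list alone, adjusted p = 0.0142, adjusted p = 0.228 with an estimated correlation). Mesothelial genes were lower in 6 of 6 (adjusted p = 0.00359, adjusted p = 0.228 with an estimated correlation). Erythroid genes were lower in 5 of 7 (adjusted p = 1.35e-06, adjusted p = 0.228 with an estimated correlation). Wnt genes were higher in 5 of 9 (adjusted p = 0.0187, adjusted p = 0.228 with an estimated correlation). Hbb-bs, Hbb-bt and Hbb-b2 were at 0 at P56, at least 1877-fold, 1844-fold and 1807-fold lower. The test called 3733 genes, 1455 higher and 2278 lower. This split depends on the scaling. Of the calls, 39.0% were higher on the deposited values, where the median change of all genes was -0.12. With median-of-ratios scaling 43.3% were higher (1619 higher and 2123 lower, median -0.05), and with edgeR 50.1% (2164 and 2152). These p-values take their spread from the other stages, and the P56 library stood apart, with the lowest sum of values (769260) and the lowest share in its 10 most abundant genes (11.5%), so age is not separated from this library. Across genes, which are not independent replicates, the Spearman correlation was 0.80 to 0.81 between the P56 and P28 libraries, 0.84 to 0.85 between P7 and P28 and 0.94 to 0.96 within a stage.

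The cell types, which may share animals (Xist, below), shared many changes from E18.5 to P28. Of 10391 genes tested in both, 685 rose in both and 529 fell in both, where independent lists would share 234 and 169. The overlap was tested across genes, which are not independent (Fisher's exact test, odds ratios 7.39 and 7.11, p = 4.78e-210 and 3.00e-168). Opposite changes were called in 159 genes, 42 higher in the epithelium and lower in fibroblasts and 117 the other way, against 398 by independence. Ranked by the smaller of the changes in the cell types, the first 8 shared rises were of H2-Eb1, Ms4a1, Cd53, Cxcl3, Cxcl2, Ccl5, Cxcl10 and Cd3d, several of them genes of leukocytes. In fibroblasts the leukocyte list had 2 of 4 higher and 0 lower and did not pass (adjusted p = 0.363). The log2 changes correlated across genes with a Pearson r of 0.44 and a Spearman rho of 0.43. Without epithelial P28 replicate 2 the number of genes changed in the same direction was 796 in place of 1214.

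The difference between the cell types in the change from E18.5 to P28 was itself tested, and 2018 genes passed. Of these, 700 had the larger rise or smaller fall in the epithelium and 1318 in fibroblasts (471 and 909 with edgeR, and 1313 in all with DESeq2). Fstl1 fell in the epithelium from 7923 ± 566 to 15.9 ± 2.05 joint CPM and was at 4905 ± 832 and 4627 ± 988 in fibroblasts (difference -8.78 (SE 0.27), adjusted p = 8.58e-15). Msln went from 419 ± 0.634 to 2.18 ± 1.59 in the epithelium and from 8.76 ± 0.155 to 27.4 ± 9.19 in fibroblasts (-8.64 (SE 0.74)). Scgb3a1 went from 5.85 ± 6.48 to 3963 ± 1449 in the epithelium and from 0 to 2.14 ± 0.245 in fibroblasts (7.91 (SE 1.43), a value that depends on the pseudocount). In fibroblasts complement and chemokine genes rose more in 11 of 13 (adjusted p = 2.42e-10, adjusted p = 9.62e-04 with an estimated correlation). Adventitial genes did so in 10 of 13 (11 adjusted over the list alone, adjusted p = 5.72e-12, adjusted p = 4.94e-04 with an estimated correlation). Cell cycle genes were raised in the epithelium relative to fibroblasts in 7 of 20 (10 adjusted over the list alone, adjusted p = 7.55e-06, adjusted p = 0.0382 with an estimated correlation).

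The same test for E18.5 to P0.5 called 472 genes, 208 in favour of the epithelium and 264 of fibroblasts (144 and 176 with edgeR). Ybx3 rose in fibroblasts from 5.19 ± 0.0742 to 303 ± 23.6 joint CPM and was at 6.27 ± 5.92 and 3.80 ± 1.07 in the epithelium (-5.94 (SE 0.77), adjusted p = 2.71e-04). Immediate early genes rose more in fibroblasts in 8 of 17 (11 adjusted over the list alone, adjusted p = 1.10e-11, adjusted p = 0.164 with an estimated correlation). Without epithelial E18.5 replicate 2, P0.5 replicate 1 or P0.5 replicate 2 this count was 306, 149 and 190. Without fibroblast E18.5 replicate 2, P0.5 replicate 1 or P0.5 replicate 2 it was 249, 225 and 173.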

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

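The differences between cell types, the splits of the libraries, the first length test and the fibroblast RNA test below were planned or written before their results were seen, and the leukocyte tests, the later length tests and the test of single matrix genes were chosen after. The results singled out here are those in which the change over time differed between the epithelium and fibroblasts in the test of the difference itself.

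From E18.5 to P28 that test called 2018 genes. The differences (epithelial change minus fibroblast change, log2) were 10.16 for Shisa6, 7.91 for Scgb3a1, 6.66 for Col25a1, -8.78 for Fstl1, -8.64 for Msln and -7.82 for Tecrl. Shisa6 went from 1 read over the epithelial E18.5 libraries to 15.7 ± 1.22 joint CPM at P28 and in fibroblasts from 78.7 ± 14.9 to 0, Col25a1 in fibroblasts from 247 ± 20.2 to 1 read, and Tecrl from 105 ± 23.2 to 3.30 ± 2.32 in the epithelium and from 4.44 ± 1.70 to 45.1 ± 8.66 in fibroblasts. The values for Shisa6, Scgb3a1 and Col25a1 depend on the pseudocount, since a group in each had 0 or 1 read. Median differences of the lists that passed follow, with adjusted p in brackets at the preset and then at an estimated correlation. They were 1.27 for alveolar type 2 (8 of 19 members higher, 2.35e-04, 0.0865) and 1.90 for club genes (0.00126, 0.0865). Ciliated genes were at -1.78 (0.00304, 0.108), cell cycle genes at 1.64 and MHC class II genes at 2.22 (7.37e-05, 0.0865). With count models class II members reversed, so that direction depends on the test. Only 9 type 2 and 4 club genes passed the fibroblast filter, and under 4 ciliated or class II genes. The epithelial filter passed 7 adventitial and 6 complement and chemokine genes, and under 4 mesothelial ones. Such differences partly set 1 cell type against values near the floor, and low levels understate a change. The other medians were -0.99 for immediate early (2.80e-04, 0.252), -1.10 for glucocorticoid-responsive (0.00238, 0.0865) and -0.47 for glycolysis genes (0.0323, 0.0865). Collagen and matrix genes were at -1.83 (2.93e-08, 0.0791), elastic fibre genes at -1.17 (4.58e-05, 0.0865) and mesothelial genes at -1.89 (0.00238, 0.214). Adventitial genes were at -3.14 and complement and chemokine genes at -2.71.

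From E18.5 to P0.5 the test called 472 genes, with differences of 3.82 for Tmem139, 3.21 for Mfsd2a, 3.11 for Plekha6, -5.94 for Ybx3, -5.27 for C1qa and -4.33 for Tmem35. Tmem139 fell to 0 and Mfsd2a to 2 reads in the P0.5 fibroblasts, and Tmem35 to 0 in the P0.5 epithelium, so these 3 values depend on the pseudocount. In the same form, the median difference was -2.07 for ciliated cell genes (2 of 6 lower, adjusted p 1.55e-06, 0.0881). Under 4 of these were tested in fibroblasts. For immediate early genes the median was -0.96 (1.10e-11, 0.164). Without epithelial P0.5 replicate 1 the count was 149.

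MHC class II genes rose in the epithelium from P0.5 on, and leukocyte genes were high at P28 although CD45-positive cells were depleted and gated out. Leukocytes in the sorted cells may account for part of the P28 level, since the leukocyte list rose from P7 to P28 by a median of 3.21 (adjusted p = 7.68e-10, adjusted p = 0.125 with an estimated correlation) and the class II list by 1.29 (adjusted p = 5.36e-06, adjusted p = 0.0618 with an estimated correlation). Tyrobp stood at 672 ± 43.4 and Laptm5 at 491 ± 94.3, and Ptprc is both a member of that list and a sort gene. They are argued against for P2 to P7, where 5 of 7 class II genes rose, Cd74 from 115 ± 12.7 to 431 ± 33.6, while Tyrobp went from 63.4 and 251 in the P2 libraries to 1 read. The leukocyte list had a median change of -1.24 there (2 of 9 lower, adjusted p = 5.38e-04, adjusted p = 0.345 with an estimated correlation). For that step a rise within the epithelial cells, which the stages of the design allow, stays open and was not tested. The sources were not separated for P28, nor for P0.5 to P2, where the class II median was 2.52, the leukocyte median 0.53 and the neutrophil and lymphocyte median 1.76 (2.36 with members at 0 set to their bound).

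Ribosomal protein genes, a set formed after the genes with the largest rises were seen, rose in the epithelium from E18.5 to P0.5, 41 of 80 higher and 2 lower, and the shorter ones rose most. In fibroblasts 33 of 81 were higher and 1 lower (median 0.59). Better recovery of short transcripts in the P0.5 libraries may be a cause, and the first test of it, on the shortest 10% of the other genes, gave a median of 0.17, below the 0.25 set as its limit. That set was too wide for the limit, since by longest transcript it reaches 1364 nt where the median ribosomal protein gene has 1094 nt. The 706 other genes no longer than that had a median of 0.28 (quartiles -0.28 to 0.91). By principal transcript the shortest 10% reached 1165 nt with a median of 0.15, and the 284 genes no longer than the 705 nt of the median ribosomal protein gene had 0.50 (quartiles -0.17 to 1.23). The longer members had medians of 0.59 by longest and 0.32 by principal transcript, so length and a rise of the family both stay open.

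Matrix genes fell in the epithelium between E18.5 and P28 (collagen list adjusted p = 1.43e-05, adjusted p = 0.0635 with an estimated correlation, elastic fibre list adjusted p = 2.80e-07, adjusted p = 0.0563 with an estimated correlation), and the list falls were called only after P2, where they were also lost with an estimated correlation. RNA of fibroblasts in the E18.5 libraries may account for part of it. The 15 called matrix genes stood at a median of 2.17% of the fibroblast level at E18.5 (quartiles 0.974% to 17.5%) and 11 mesenchymal genes outside those lists at 2.07% (1.40% to 3.94%), a ratio of 1.05 where a ratio of 3 had been set as the limit. The medians were 1.55% and 1.45% at P0.5, 2.18% and 1.92% at P2 and 0.290% and 0.261% at P28, so the level was not special to E18.5, whose epithelial label lacks the GFP gate. Fibroblast RNA is argued against for 5 of the 15 members above the mesenchymal range, Fbln5 (107% of the fibroblast level), Fbn2 (126%), Col6a1 (31.7%), Col6a2 (19%) and Ltbp4 (16.0%). In each the lowest epithelial over the highest fibroblast library at E18.5, 12.9% or more, was above the highest mesenchymal value, 10.2% for Pdgfrb. For these 5, expression in the epithelial cells that falls with stage, or RNA of other cells, stays open and was not tested.

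The 8349 genes that differed between cell types were set against other stage-balanced splits of the 20 libraries. Of 100 splits, the real one included, 1 called as many, and the others at most 2999. The sort made the groups differ, so nothing is concluded.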

How the results depend on the processing

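The fits without E18.5, P28 or P56 and the block within stages were chosen after seeing the data, and the other alternatives before. Of 270 counts of genes recomputed for 17 results, 229 stayed within 1.5 times, and 41 moved, 35 of them when 1 library was left out. These ranges were 616 to 1118 for epithelium E18.5 to P0.5, 109 to 775 for P0.5 to P2, 140 to 431 for P2 to P7, 406 to 566 for P7 to P28 and 1838 to 2347 for E18.5 to P28. In fibroblasts they were 676 to 1354, 789 to 1129, 262 to 514 and 1548 to 2032 for the 4 steps from E18.5 to P28. They were 149 to 448 for the cell type difference at birth and 796 to 1085 for the overlap. Such fits have fewer libraries and 1 residual degree of freedom less. With no filter on low values the counts were 578 for epithelium P0.5 to P2, 211 for epithelium P2 to P7, and 1113, 1254 and 359 for fibroblasts E18.5 to P0.5, P0.5 to P2 and P2 to P7, with more low genes tested. DESeq2 called 1313 genes for the cell type difference from E18.5 to P28, and the cause was not tested. In that difference MHC class II genes reversed, with edgeR at -0.27 for Cd74, -1.12 for H2-Aa and -1.07 for H2-Ab1 and with DESeq2 at -0.59, -0.44 and -0.41, and Sftpa1 was at -0.065 with edgeR. None reversed with a pseudocount of 0.5 or 5, and the cause was not tested. Without E18.5 or P28, 7843 and 7922 genes differed between cell types, 3077 and 3306 among epithelial stages and 4849 and 4361 among fibroblast stages, and 5793 fibroblast genes differed among stages without the P56 library.

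The replicate numbers were not taken to pair the libraries, because same-numbered libraries did not all deviate together. Deviations of same-numbered libraries from their group means correlated at -0.06 to 0.07 between stages of a cell type (20 pairs) and -0.19 to 0.24 between cell types at a stage (5 pairs, of which P0.5, P2 and P7 were above 0.1). With the number as a block the counts were 8351 for the cell types, 1797, 1068, 454, 885 and 2997 for the epithelial comparisons in the order above, 1827, 2035, 822, 2508 and 4028 for the fibroblast ones, 4305 and 5886 for any stage, 2020 and 463 for the interactions and 1214 for the overlap. A block for same-numbered libraries of both cell types within each stage gave 8311 for the cell types and 1903 and 428 for the interactions, and ended none of the 37 list calls of these fits. The block was not run for P28 to P56, where P56 has 1 library. Of 164 list calls fry ended 13 and an estimated correlation 128. The replicate block ended 0 of the 155 it was run on and median-of-ratios scaling 0 of 163, and leaving out 1 library ended 46 of 1046. Of 11507 values for 720 pairs of a named gene and a comparison, 10958 kept their direction and side of the threshold, 523 lost the threshold, 19 gained it and 7 reversed.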

Other observations

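No test here was planned. Xist, the RNA of the inactive X chromosome, was higher in replicate 2 in both cell types at P28, P7 and P2. At P28 this 1 gene argues against technical repeats. Replicates 1 and 2 were at 12.7 and 322 in the epithelium and 12.4 and 552 in fibroblasts at P28, at 224 and 351 and at 411 and 785 at P7, and at 180 and 414 and at 696 and 1535 at P2. At E18.5 they were at 386 and 377 in the epithelium and 1487 and 1716 in fibroblasts, and at P0.5 at 129.6 and 122 and at 454 and 421. The Y-linked genes Ddx3y and Uty were in the epithelial tables, with stage means of 4.14 to 15.1 and 4.03 to 18. Haemoglobin genes took 1.3% of the reads of epithelial P2 replicate 2 and 0.00966% and 0.0547% of the epithelial P7 libraries.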
